A study of Mus musculus with 9 samples.

How the data were processed

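Lung tissue of mice was profiled on 9 expression arrays, 3 of a control group, 3 after injection of lipopolysaccharide (LPS) and 3 after mechanical ventilation at high pressure, and the table of all 9 samples was used. The maker of the array, the number of dyes, the scanner and the processing before deposit are not given in the sources used here. The values in the deposited table are ratios on a linear scale, as tested on the values themselves. In every one of the 10012 probes the mean of the 3 control log2 ratios was 0, with a largest absolute deviation of 2.5e-09, so each probe had been divided by the geometric mean of the 3 control arrays. No level of one probe against another is left in such values, and the scaling between arrays remains unknown. The deposited ratios also carried a floor. At 4690 probes 2 or more arrays held values of 1 fixed pattern over the arrays (tolerance 1e-06 on the log2 scale), at 2782 of them 2 to 8 arrays and at the rest all 9, and these were the lowest values of their row at all but 1 probe, so a higher ratio was read as a higher signal. Each array thus has its own floor, given here as a ratio: 0.709, 1.07 and 1.317 on control arrays 1 to 3, 0.957, 0.981 and 0.989 on LPS arrays 1 to 3, and 0.981, 0.801 and 2.222 on overventilation arrays 1 to 3. The medians of the deposited values were 0.844, 1.07 and 1.085 for the controls, 0.957, 0.981 and 0.989 for LPS, and 0.981, 0.819 and 1.704 for overventilation. For 5322 probes no 2 arrays were at the floor and their distance from it is unknown.

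The plan fixed before the data were examined assumed signal intensities, with a floor and a filter set at percentiles of all values. Ratios have no such percentiles in common, so the test was kept and these rules were replaced. Where the level was known, values were raised to the highest of the 9 floors, that of overventilation array 3 (a ratio of 2.222, or 1.152 on the log2 scale), and set relative to the control mean again. A probe was tested if it lay above that floor on 3 or more of the 9 arrays, or if no 2 of its arrays were at a floor, which left 5710 probes. No normalization between arrays was added. A fold change of a probe near the floor is therefore too small, and where a whole group lay at the floor it is a lower bound.

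Gene names came from the annotation table of the array's platform. A single gene symbol was given for 8983 probes, several for 1 and none for 1028, which are unnamed here. The named probes stood for 8841 genes, 138 of them with more than 1 probe. The gene ID of 8975 probes was found in the reference gene table, and no symbol needed an update. No genome build is named in the sources used here, so no coordinates are given. Where 1 probe per gene was needed, the one above the floor on most arrays was taken, then the one with the lowest probe number, which left 5089 genes. At 66 genes with 2 tested probes, the median correlation of both probes over the 9 arrays was -0.034, against 0.036 for 2000 random pairs of probes. A gene's value is therefore the value of 1 probe, which a second probe of the same gene did not generally follow. Pairs of genes within fixed lists did move together in some lists, with median correlations of 0.282 in the interferon list, 0.534 in the NF-kB list and 0.709 in the adipose list, and of 0.057, 0.474 and 0.564 within groups. In other lists called below they hardly did, with 0.044 over the 9 arrays in the chemokine list and 0.012 in the oxidative phosphorylation list.

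Group means of log2 ratios were compared with limma 3.58.1 in R 4.3.3 (lmFit on the 3 groups, contrasts, eBayes with default settings, two-sided), with all 9 arrays sharing 1 estimate of spread per probe. P-values were adjusted by the Benjamini-Hochberg method over the probes of a contrast, with a threshold of 0.05. The 3 contrasts were overventilation against control, LPS against control and overventilation against LPS, and a moderated F test over the 3 groups was added. The study's labels number the samples of each group, and the fit has no block for that number. Correlations of same-numbered arrays' deviations from their group means were 0.497, 0.247 and 0.199 for LPS and control, all above 0.1, so for this comparison the numbers were taken to pair the arrays on the data alone. For overventilation and control they were 0.508, 0.133 and 0.033, and for overventilation and LPS 0.496, 0.211 and 0.038. Deviations from a group mean cancel out within the group. A deviation shared by the arrays numbered 1 alone can therefore raise the correlations of the other numbers, so these values do not establish a pairing.

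Of 41 gene lists fixed before the data were examined, 40 held 3 or more tested genes. They were 24 lists of response pathways and 16 of markers of cell types and tissues. Each was tested with limma's camera at a preset correlation between genes of 0.01, which compares the list with all other genes, adjusted over the 40 lists of a contrast. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Genes are named in the text by a rule fixed before the data were examined. It takes the 8 highest and 8 lowest changes past the threshold in each contrast or, where none passes, the 5 highest and 5 lowest among probes whose groups do not overlap. It adds up to 4 members with the smallest p of each list described, and 12 genes fixed by name. The correlation of both treatment effects was set beside 100 simulations of unchanged groups against the same controls.

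The test was run on simulated data with the spread of these arrays. At a log2 change of 2 it found 58% of the changed probes for overventilation against control, 50% for LPS against control and 62% for overventilation against LPS, and at a log2 change of 1 it found 6%, 4% and 8%. The number of arrays limits the precision. The real arrays differ in spread, with an SD of 0.365 to 1.257 over probes with no 2 arrays at the floor. Arrays numbered 1 also deviated together, so these shares may not hold for the real arrays. The alternatives were quantile normalization, scaling of the arrays to the same median, an offset or the deposited floors in place of the common floor, no filter, a trended and robust prior, only the arrays of both groups compared, array weights, the replicate block and each array left out in turn. Chosen after the data were seen were a fit with lone low spots set to missing (values over 1.5 on the log2 scale below all other arrays), a fit on probes without floored arrays, and a fit without overventilation array 3 at the next highest floor. Figures were drawn with matplotlib 3.10.9.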

Results

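The series concerns ventilator-induced lung injury, the damage that mechanical ventilation can do to the lung. RNA levels in mouse lung tissue were measured on 9 arrays in 3 groups of 3. One group received an injection of E. coli lipopolysaccharide, a component of the bacterial outer membrane, at 3 mg/kg. A second was ventilated at a pressure of 25 cmH2O for 3 h, which the study calls overventilation, and the third served as control. The labels do not state how the controls were handled, nor whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The deposited values are ratios to the control mean, and levels are given here on the log2 scale as mean ± SD, with the control mean at 0. Of 10012 probes, 5710 were tested, and 4690 lay at the floor on at least 2 arrays. The floor was highest on overventilation array 3, where 42.4% of probes were at it, against 27.8% to 39.4% on the other arrays.

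The comparison of overventilation with control asks which transcripts differ in lungs ventilated at high pressure. Among the genes fixed by name, Ccl2, Il6, Cxcl1 and Il11 had higher mean levels in the overventilated lungs, although no single probe passed the test over all probes and neither the chemokine list (adjusted p = 0.187) nor the cytokine list (adjusted p = 0.14) did. Ccl2, which encodes a chemokine that attracts monocytes, stood at 2.87 ± 0.94 (SD, n = 3) after overventilation and at 0 ± 0.70 in controls, a 7.32-fold difference with a limma adjusted p of 0.193. Il6, a cytokine of the acute phase response, stood at 2.23 ± 0.40 against 0 ± 0.28 (4.68-fold, adjusted p = 0.306). The neutrophil chemokine Cxcl1 stood at 1.42 ± 0.31 against 0 ± 0.11 (2.67-fold, adjusted p = 0.329), and Il11, a cytokine of the interleukin 6 family, at 2.02 ± 0.62 against 0 ± 0.72 (4.06-fold, adjusted p = 0.193). For each of these 4 genes all 3 overventilated samples lay above all 3 controls.

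The 5 highest changes among probes without overlap were those of Cxcl10, Slc25a5, Tnfrsf12a, Akap12 and Mx2, none of which passed the test (adjusted p = 0.193 for each). The interferon-induced chemokine Cxcl10 had a log2 change of 3.55 with a standard error of 0.89, Slc25a5, a mitochondrial ADP/ATP carrier, 3.48 with a standard error of 0.82, and Tnfrsf12a, a receptor of the TNF superfamily, 3.43 with a standard error of 0.72. On overventilation array 3 these 3 genes lay at 5.23, 5.04 and 5.24, and on arrays 1 and 2 between 2.38 and 3.01. Array 3 held 100 lone high values (over 1.5 above all other arrays), against at most 6 on any other array. The scaffold protein gene Akap12 changed by a log2 value of 3.31 with a standard error of 0.72 and the interferon-induced GTPase gene Mx2 by 3.08 with a standard error of 0.61. Of the other genes fixed by name, Plaur, the urokinase receptor gene, had a log2 change of 2.28 (adjusted p = 0.386), the prostaglandin synthase gene Ptgs2 1.36 (0.318) and the heme oxygenase gene Hmox1 0.75 (0.445), each without overlap of the samples. Ptgs2 lay at 0.46, 0.75 and 2.88 on overventilation arrays 1 to 3, so the last of these carries much of its mean. The samples overlapped for Il1b, with a log2 change of 0.55 (adjusted p = 0.694). Tnf was at the floor on all 9 arrays, and Cxcl2 and Areg were not analysed here.

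**Figure D1:**
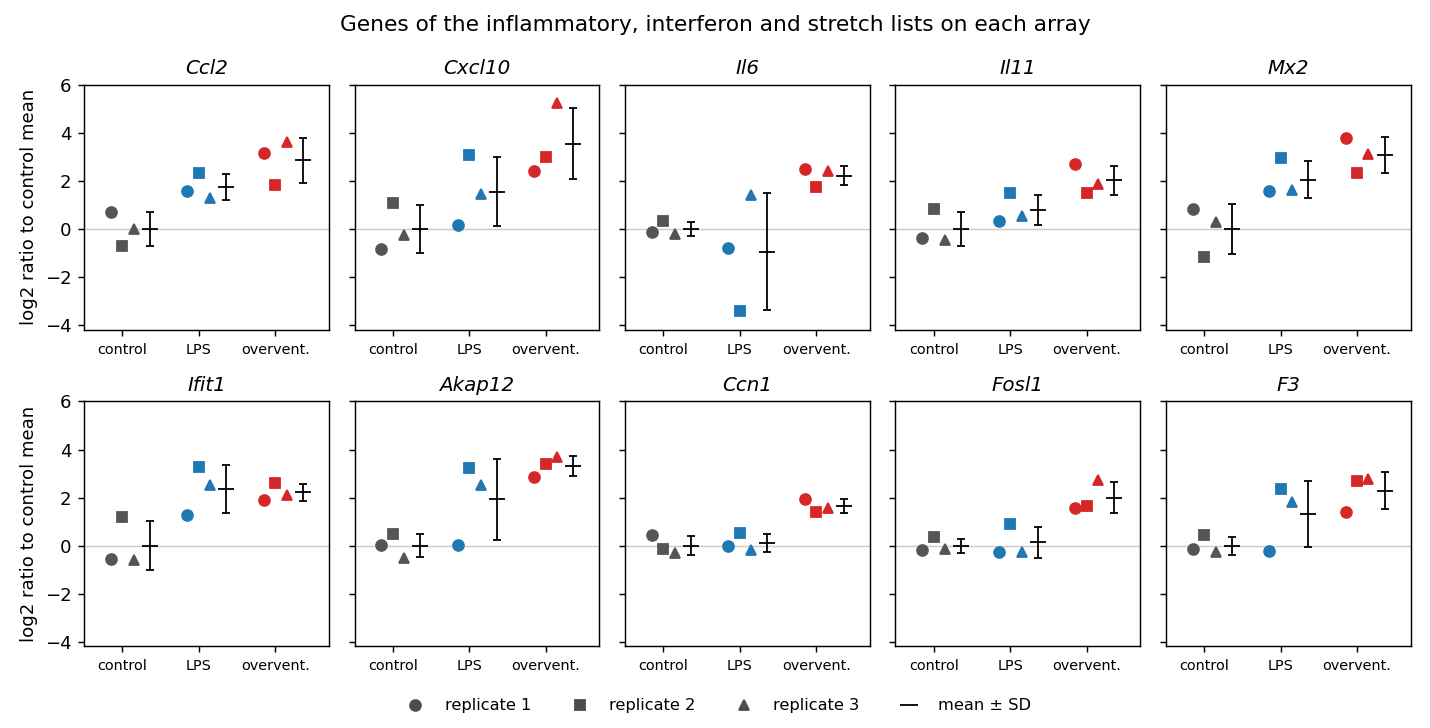
Log2 ratio to the control mean (y axis) of 10 named genes on each of the 9 arrays, by group (x axis), with marker shape for the replicate number and a bar for the mean ± SD of each group. Ccl2 lay between 1.82 and 3.62 on the overventilation arrays, all above the 3 controls, while Il6 ranged from -3.43 to 1.41 on the LPS arrays.

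Among the gene lists, 7 of 40 rose in overventilated against control lungs by camera at the preset correlation, and none fell. Interferon response genes rose with a median log2 change of 1.01 over 20 genes (adjusted p = 0.000101, and adjusted p = 0.245 with an estimated correlation). Adjusted over the list alone, 5 of its members were higher and 1 was lower, while over all genes tested the count was 0. Mx2, the GTPase gene Irgm1 (log2 change 2.39), Ifit1 (2.21) and the signal transducer gene Stat2 (1.81) were the members with the smallest p, and the lower one, named after its values were seen, was the immunoproteasome subunit gene Psmb10 (-1.35, with -2.38 on overventilation array 3). Immediate early genes, which are transcribed within minutes of a stimulus, rose with a median of 0.71 over 17 genes (adjusted p = 0.000329, and adjusted p = 0.245 with an estimated correlation). Adjusted over the list alone, 7 of them were higher and none lower, with log2 changes of 1.99 for Fosl1, 1.97 for Arc, 1.37 for Klf4 and 1.91 for Ier2. Ier2 had a lone low value on control array 3, and its change without that value was 1.30.

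The list of stretch-responsive genes rose with a median log2 change of 1.06 over 13 genes (adjusted p = 0.000674, and adjusted p = 0.378 with an estimated correlation), and adjusted over the list alone 6 members were higher and none lower. Its leading members were the matricellular protein gene Ccn1 at 1.64 ± 0.28 (SD, n = 3) against 0 ± 0.40 in controls, Akap12, the matrix glycoprotein gene Tnc with a log2 change of 1.88 and the annexin gene Anxa1 with 1.63. The NF-kB list rose with a median of 0.77 over 12 genes (adjusted p = 0.00158, and adjusted p = 0.513 with an estimated correlation). All 12 NF-kB members were on the higher side, 3 of them past the threshold adjusted over the list alone, and the log2 changes of Tnip1, Nfkb2, Birc3 and Cd40 were 1.68, 1.59, 1.66 and 1.79. Feedback inhibitors of MAPK and JAK-STAT signalling rose with a median of 0.89 over 15 genes (adjusted p = 0.00185, and adjusted p = 0.513 with an estimated correlation), with log2 changes of 1.94 for Spry4, 2.01 for Errfi1, 1.05 for Dusp1 and 1.28 for Socs3. Adjusted over the list alone, 3 of the feedback genes were higher.

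Coagulation and fibrinolysis genes rose with a median log2 change of 0.95 over 8 genes (adjusted p = 0.00634, and adjusted p = 0.245 with an estimated correlation). F3, which encodes tissue factor, stood at 2.28 ± 0.77 (SD, n = 3) against 0 ± 0.37 in controls, and Anxa2, a cell surface receptor of plasminogen activation, at 1.68 ± 0.53 against 0 ± 0.67. These 2 were higher when adjusted over the list alone. F2r, the thrombin receptor gene, had a log2 change of 0.75, with 1.47 on overventilation array 3 and 0.37 and 0.42 on the others. Without overventilation replicate 1 the median of the coagulation list was 1.43. The list of oxidative stress genes and NRF2 targets rose with a median of 0.75 over 15 genes (adjusted p = 0.04, and adjusted p = 0.513 with an estimated correlation). Gclc, the rate-limiting enzyme of glutathione synthesis, had a log2 change of 2.06, the thioredoxin reductase gene Txnrd1 2.02 and the peroxiredoxin gene Prdx1 1.14, while the glutathione transferase gene Gsta4 stood at -2.36. Adjusted over the list alone, 3 members were higher and 1 was lower. Without overventilation replicate 3 the median of the oxidative stress list was 0.18.

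**Figure D2:**
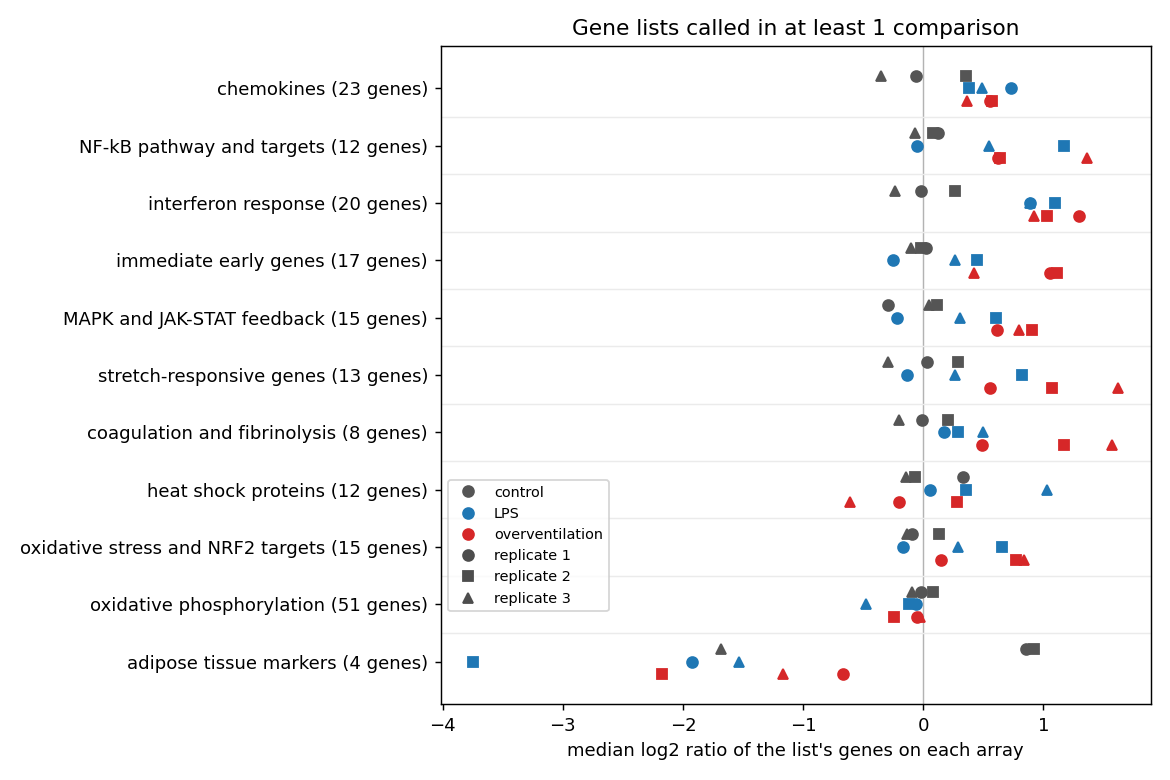
Median log2 ratio (x axis) of the genes of each list on each of the 9 arrays, for the 11 lists called in at least 1 comparison (y axis), with colour for the group and marker shape for the replicate number. The interferon list lay between 0.93 and 1.29 on the overventilation arrays and between -0.24 and 0.26 on the controls, and the adipose list lay at -1.68 on control array 3.

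The 5 lowest changes without overlap belonged to Nr2f2, a nuclear receptor gene (log2 change -3.73), Atp5l, a subunit of ATP synthase (-3.41), Cstf2t (-3.16), the co-chaperone gene Bag1 (-3.16) and Ndufa5 (-3.11), with adjusted p between 0.193 and 0.273. The first 4 were among 139 probes that on overventilation arrays 1 and 3 lay more than 1.5 below all 7 other arrays. The medians of these 139 probes were -2.95 on overventilation array 1, -0.20 on array 2 and -3.14 on array 3, and Gsta4 was one of them. Ribosomal protein genes had a median log2 change of -0.27 over 52 genes (adjusted p = 0.0502), which did not pass. The lowest adjusted p of a single probe was that of Mmp11, a matrix metalloproteinase, with a log2 change of -2.35 and a standard error of 0.30 (adjusted p = 0.0828), a gene named after its values were seen.

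Of the 16 marker lists none passed the test for overventilation against control. Adipose tissue markers had a median log2 change of -1.32 over 4 genes (adjusted p = 0.053), with control array 3 at -1.68 and the other controls at 0.86 and 0.92, and neutrophil markers one of -0.31 over 6 genes (adjusted p = 0.617). Alveolar type II markers had a median of -0.13 over 8 genes (adjusted p = 0.835). Among these Napsa, the napsin A gene, had a log2 change of -2.13 at 1 probe and 0.48 at a second. The chemokine list did not pass either, with a median of 0.64 over 23 genes (adjusted p = 0.187). Ccl3 (log2 change 2.75), Ccl2 and Cxcl10 were among its highest members, and Cxcl14, at -2.99, belonged to the 139 probes above. So did Ccl17, named after its values were seen, with -2.47, 0.54 and -4.00 on overventilation arrays 1 to 3.

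The count of probes changed between overventilation and control was 0 by limma at an adjusted p under 0.05, with 850 probes at an unadjusted p under 0.05, 354 of them higher and 496 lower, where 285.5 would be called by chance. That number was 401 with quantile normalization, 549 without control replicate 3 and 483 without overventilation replicate 3, and without overventilation replicate 1 it was 504 higher and 335 lower. The samples of both groups did not overlap at 19.6% of probes, where chance gives 10%. Without overventilation replicate 2 the test called 290 probes, 271 of them lower and among these the 139 probes low on the other overventilation arrays. Without control replicate 3 it called 1, the adipose marker Retn. On that control array Retn lay at -1.90, near the overventilation arrays (-2.21 on each), and on the other controls at 0.97 and 0.93. Without overventilation replicate 3 the number of lists called went from 7 to 11. By fry 3 lists passed, the interferon, immediate early and coagulation lists, and the call of the oxidative stress list ended without control replicate 1 (adjusted p = 0.0691), control replicate 3 (0.0607) or overventilation replicate 2 (0.255), within a range of 0.00589 to 0.255 over the 21 alternatives that keep the preset correlation. With no filter the medians of the NF-kB, coagulation and oxidative stress lists were 0.38, 0.52 and 0.40. With an offset in place of the floor those of the interferon, immediate early, feedback, NF-kB and oxidative stress lists were 0.67, 0.44, 0.59, 0.49 and 0.48. The NF-kB median was 1.30 with lone low spots set to missing, and at the lower common floor without overventilation array 3 the stretch median was 0.69 and the oxidative stress median 0.18.

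The comparison of LPS with control asks what injected endotoxin alone changes in the lung. Interferon response genes had the smallest adjusted p of the 40 lists. They rose with a median log2 change of 0.80 over 20 genes (adjusted p = 5.85e-10, and adjusted p = 0.0517 with an estimated correlation), and the list's median lay at 0.89, 1.10 and 0.89 on the 3 LPS arrays against at most 0.26 on a control array. With no filter, where genes mostly at the floor count as well, the interferon median was 0.36. Ifit1 stood at 2.36 ± 1.00 (SD, n = 3) after LPS against 0 ± 1.03 in controls, a 5.12-fold difference, and Isg20, an interferon-induced exonuclease gene, had a log2 change of 1.35. Those of the antiviral GTPase genes Mx1 and Mx2 were 2.03 and 2.05. Adjusted over the list alone these 4 genes were higher, while over all genes tested none passed (adjusted p = 1).

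Chemokine genes rose with a median log2 change of 0.51 over 23 genes (adjusted p = 0.000261, and adjusted p = 0.163 with an estimated correlation), with no member past the threshold adjusted over the list alone. Ccl2 stood at 1.74 ± 0.53 (SD, n = 3) against 0 ± 0.70 in controls, a 3.35-fold difference, and Cxcl11, Ccl3 and Cxcl5 had log2 changes of 1.81, 1.38 and 1.23. The chemokine median was 0.33 without control replicate 1 and 0.30 with an offset. The NF-kB list rose with a median of 0.49 over 12 genes (adjusted p = 0.00105, and adjusted p = 0.42 with an estimated correlation). Its median lay at -0.06 on LPS array 1, inside the range of the controls (-0.06 to 0.13), and at 1.18 and 0.55 on LPS arrays 2 and 3. In it the antioxidant enzyme gene Sod2 stood at 1.32 ± 0.82 (SD, n = 3), Cd40 at 1.13 ± 1.48, with 2.83 on LPS array 2, and the apoptosis inhibitor gene Birc3 at 1.04 ± 0.63. The NF-kB median was 0.30 with no filter, 0.90 without LPS replicate 1 and 0.25 without LPS replicate 2. Coagulation and fibrinolysis genes rose with a median of 0.66 over 8 genes (adjusted p = 0.00592, and adjusted p = 0.163 with an estimated correlation), with F3 at 1.33 ± 1.37 (SD, n = 3) and Serpinb2 at 1.20 ± 1.22, with 2.56 on LPS array 2. The coagulation median was 0.09 with no filter, 1.00 with quantile normalization, 0.41 with an offset, 0.29 without control replicate 3, 0.40 without LPS replicate 1 and 0.44 without LPS replicate 2. Heat shock protein genes rose with a median of 0.55 over 12 genes (adjusted p = 0.015, and adjusted p = 0.42 with an estimated correlation), with log2 changes of 0.72 for the chaperone gene Hspa8 and 0.95 for its cofactor gene Bag3. The heat shock median was 0.25 with no filter, 0.34 with an offset, 0.92 with array weights, 0.28 without control replicate 3 and 0.15 without LPS replicate 3.

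The feedback inhibitors of MAPK and JAK-STAT signalling (median 0.13 over 15 genes) and the stretch-responsive genes (median 0.33 over 13 genes) rose after LPS with an adjusted p of 0.0445 each, and adjusted p = 0.42 with an estimated correlation for both. On LPS array 1 the medians of both lists were below 0, at -0.22 and -0.14. Dusp6 and Socs1 had log2 changes of 2.00 and 1.26, and Akap12 one of 1.92. Without LPS replicate 2 the feedback median turned to -0.07 and the stretch median was 0.08, and without LPS replicate 1 they were 0.56 and 0.63. The feedback median was 0.09 without control replicate 1, 0.29 without control replicate 2 and 0.20 without LPS replicate 3, and the stretch median was 0.52 without control replicate 2 and 0.16 without control replicate 3. With no filter both calls were lost, and the stretch median was 0.20, as it was with an offset, while array weights gave a feedback median of 0.29. The numbers were taken to pair the arrays of this comparison on the data alone, and no label states such pairs. With the replicate block the stretch-responsive call was lost (adjusted p = 0.0949, within a range of 0.00435 to 0.247 over the 21 alternatives that keep the preset correlation). The oxidative stress list (adjusted p = 0.0466) and the smooth muscle and pericyte list (adjusted p = 0.0437) were called with the block and not in the main fit (adjusted p = 0.098 and 0.13).

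Lower after LPS were the genes of oxidative phosphorylation, which fell with a median log2 change of -0.25 over 51 genes (adjusted p = 0.00441, and adjusted p = 0.163 with an estimated correlation), 43 of the 51 lying on the lower side and the median at -0.13 with an offset. Over all tested probes the median change was -0.05. The list lay at -0.06 on LPS array 1, inside the range of the controls (-0.09 to 0.08), at -0.12 on array 2 and at -0.48 on array 3. The complex I subunit genes Ndufa7 and Ndufb3 had log2 changes of -1.41 and -0.86, and that of Ndufa7 was -0.57 without its lone low value on LPS array 2. Adipose tissue markers fell with a median of -2.54 over 4 genes (adjusted p = 8.01e-06, and adjusted p = 0.192 with an estimated correlation). The log2 changes were -3.32 for the adiponectin gene Adipoq, -2.98 for Fabp4, -2.09 for Retn and -1.14 for Ucp1, and adjusted over the list alone all 4 were lower. Ucp1 was at the floor on the 3 LPS arrays, and LPS array 2 held lone low values of Adipoq and Fabp4, whose changes without it were -2.34 and -1.43. The adipose median was -1.62 with no filter, -0.99 with an offset and -1.61 with array weights. The adipose list lay at -1.68 on control array 3 and at 0.86 and 0.92 on control arrays 1 and 2.

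The 5 highest changes without overlap after LPS were Cep55, a cytokinesis gene, with a log2 change of 2.40, then Ifit1, Mx2, Mx1 and Dusp6. The 5 lowest were Adipoq, 1110059G10Rik (-2.91), Ube2r2 (-2.45), Naa38 (-2.22) and Shank3 (-2.21), and in 4 of these 5 the value of LPS array 2 lay more than 1.5 below all other arrays, as it did at 291 probes in all. Without that value the changes of Ube2r2, Naa38 and Shank3 were -0.23, -0.49 and -0.45. Of the genes fixed by name, Il6 stood at -0.94 ± 2.42 (SD, n = 3), with a single low value on LPS array 2, and at a log2 change of 0.31 with that value left out. Cxcl1 stood at 0.99 ± 1.52, Il1b at 0.35 ± 1.04 and Il11 at 0.79 ± 0.61, and Plaur, at 1.72 ± 2.72, lay at 4.65 on LPS array 1. Ptgs2 stood at 0.00 ± 0.49 and Hmox1 at 0.18 ± 0.78. Neutrophil markers had a median of -0.36 over 6 genes (adjusted p = 0.417), and none of the marker lists other than the adipose one passed.

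The count of probes changed between LPS and control was 0 by limma, with 118 probes at an unadjusted p under 0.05, 57 higher and 61 lower, which is below the 285.5 that chance gives, and 314 with the replicate block. That number was 37 with a trended and robust prior (29 higher, 8 lower), 420 with array weights, 56 without control replicate 3 and 457 without LPS replicate 1 (150 higher, 307 lower), and without control replicate 2 it was 120 higher and 41 lower. The samples did not overlap at 6.3% of probes, where chance gives 10%. Without control replicate 3 the test called 1 probe, again Retn, with a log2 change of -3.04. On control array 3 this adipose marker lay at -1.90, near the LPS arrays (-2.12, -2.21 and -1.95). On control arrays 1 and 2 it lay at 0.97 and 0.93, so the call rests on leaving out the control near the LPS arrays. Of 9 lists called, 7 higher and 2 lower, 3 were called without LPS replicate 3, 14 without LPS replicate 1, and 18 with array weights, and by fry or with an estimated correlation the count was 0. At the preset correlation the interferon and chemokine calls held in 21 of 21 alternatives and the adipose call in the 19 that gave it a value, while without LPS replicate 3 the other 6 were lost, NF-kB also without LPS replicate 2, heat shock without control replicate 2 or 3, feedback without control replicate 1 or LPS replicate 2, and the stretch list without control replicate 1 or 3, LPS replicate 2 or overventilation replicate 3. The stretch list was called in 11 of 21 alternatives and the feedback list in 14.

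Overventilation and LPS were compared to ask where both injuries differ. The time after the LPS injection is not given here, so their differences could not be separated from the time since the stimulus. Immediate early genes were higher after overventilation than after LPS, where they rose with a median log2 difference of 0.45 over 17 genes (adjusted p = 0.0138, and adjusted p = 0.983 with an estimated correlation). Fosl1 stood at 1.99 ± 0.65 (SD, n = 3) after overventilation and at 0.13 ± 0.66 after LPS, and Arc at 1.97 ± 0.65 and -0.04 ± 0.76. The nuclear receptor gene Nr4a1 differed by 1.66 and Klf4 by 1.22, and adjusted over the list alone 5 members were higher. The median was 0.82 without LPS replicate 2, 0.70 without overventilation replicate 3 and 0.26 with an offset. The stretch-responsive genes rose with a median difference of 1.02 over 13 genes (adjusted p = 0.0315, and adjusted p = 0.983 with an estimated correlation). Ccn1 stood at 1.64 ± 0.28 after overventilation and at 0.11 ± 0.37 after LPS and was the only member past the threshold adjusted over the list alone, while Tnc, Anxa1 and the focal adhesion gene Zyx differed by 1.31, 1.18 and 1.13. The stretch median was 0.36 with no filter, 0.59 with quantile normalization, 0.35 without overventilation replicate 3 (0.32 at the lower floor) and 0.60 without LPS replicate 1.

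The interferon list did not differ past the threshold, with a median of 0.16 over 20 genes (adjusted p = 0.918), nor did the NF-kB list, with 0.41 over 12 genes (adjusted p = 0.456). The chemokine list, called for LPS and not for overventilation, did not differ between them either, with 0.165 over 23 genes (adjusted p = 0.918). The 5 highest differences without overlap were Il6 (3.17, adjusted p = 0.494), Tnfrsf12a (2.90), Rps2 (2.72), Snx3 (2.61) and Shank3 (2.53). In 4 of the 5, all but Tnfrsf12a, LPS array 2 held a lone low value, and without it the difference was 1.92 for Il6, 0.76 for Rps2, 1.06 for Snx3 and 0.78 for Shank3. The 5 lowest were Nr2f2 (-3.32), Cstf2t (-3.22), Atp5l (-3.20), the COP9 signalosome gene Cops2 (-2.96) and the chromatin remodeller gene Smarca5 (-2.86), all of them among the 139 probes low on overventilation arrays 1 and 3. A second probe of Smarca5 differed by -0.01. Il11 differed by 1.24 (adjusted p = 0.494), Ccl2 by 1.13 (0.541), Ptgs2 by 1.36 (0.511, with 2.88 on overventilation array 3), Hmox1 by 0.58 (0.656), Plaur by 0.56 (0.879), Cxcl1 by 0.43 (0.843) and Il1b by 0.20 (0.91). The last 4 differences depend on LPS arrays 1 and 2, which held the lowest and highest LPS values of each of these genes. On LPS arrays 1 to 3 Hmox1 lay at -0.58, 0.99 and 0.12, and Plaur at 4.65, -0.72 and 1.23. Cxcl1 lay at -0.66, 2.32 and 1.32 there, and Il1b at -0.84, 1.09 and 0.79.

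Between overventilation and LPS limma called 0 probes, with 543 at an unadjusted p under 0.05, 204 higher and 339 lower, where chance gives 285.5, and 226 were called without overventilation replicate 2. The number at an unadjusted p under 0.05 was 217 with quantile normalization, 840 with the replicate block, 181 without overventilation replicate 3 and 825 without overventilation replicate 2, and without overventilation replicate 1 it was 320 higher and 157 lower. The samples did not overlap at 11.2% of probes, where chance gives 10%. Both list calls were lost without LPS replicate 1 or overventilation replicate 2 (0 lists), at the preset correlation with adjusted p of up to 0.476 for the immediate early and 0.718 for the stretch-responsive genes. Without LPS replicate 2 the count was 5 and without overventilation replicate 1 it was 1, as it was with quantile normalization and with array weights, and fry called 0. By the F test over the 3 groups, 0 probes passed and 591 had an unadjusted p under 0.05. Without overventilation replicate 2 that test called 200 probes, and without control replicate 3 it called 1.

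Across 5089 genes, which are not independent replicates, the changes after overventilation and after LPS had a Pearson correlation of 0.46 and a Spearman correlation of 0.49. Unchanged groups set against the same 3 controls gave a mean correlation of 0.50 and a highest one of 0.54. The simulation treats the samples as independent, although arrays numbered 1 deviated together, and it was run for 1 setting only. It also gives each probe the same spread in all 3 groups, which puts the simulated correlation near 0.50. The real SD over probes with no 2 arrays at the floor was 0.365 to 0.514 on control arrays and 0.618 to 1.257 on the others. An unknown part of that gap follows from division by the control mean. The simulations therefore do not decide whether the treatments share more than the controls explain. The observed correlation was 0.56 with quantile normalization, 0.57 with an offset in place of the floor and 0.57 without control replicate 2, and as low as 0.33 without overventilation replicate 2, so no comparison with the simulations is drawn for those. The covariance was 0.20 against 0.17 in the simulations, a difference of 0.035. At an unadjusted p under 0.05, 322 genes were higher after overventilation and 52 after LPS, with 26 in common where independent lists would share 3.3. Among the lower genes, 452 and 52 shared 26 where 4.6 would be shared. The 3 controls could not be split, so the part of this excess that comes from them is unknown.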

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

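Chosen after the data were seen were 3 alternatives, namely lone low spots set to missing, only probes without floored arrays, and a lower common floor without overventilation array 3, which left all counts of probes at 0. No result reversed its direction past the threshold under any alternative run. The floor at the pooled 40th percentile and the filter at the pooled 60th percentile were planned but not run, since ratios have no common level. Leaving out each array in turn, probes called ranged from 0 to 290 for overventilation against control, from 0 to 1 for LPS against control, from 0 to 226 for overventilation against LPS and from 0 to 200 by the F test, and lists called from 6 to 11, from 3 to 14 and from 0 to 5 in that order of contrasts. At an adjusted p under 0.10, 1 probe was called for overventilation against control. The counts of 7, 9 and 2 lists became 0, 0 and 0 with an estimated correlation and 3, 0 and 0 with fry. For overventilation against LPS 1 list was called with quantile normalization and 1 with array weights, and for LPS against control 18 with array weights. The replicate block gave 0 probes in each contrast and 7, 10 and 2 lists, and changed no list call besides the 3 named in the report. Single lists crossed the threshold upward in 55 and downward in 34 of their tests. The causes of these shifts were not tested, except that leaving out an array leaves fewer samples. Near the floor, fold changes are limited by signal over background.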

Other observations

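Among the tests here, those on the floors, on the interferon list of LPS array 1 and on the adipose list were chosen only after the results were seen. Probes that lay at the common floor on all 3 controls and above it on all 3 overventilated samples numbered 9, and 3 did so after LPS. Cd9, a tetraspanin gene, was in both sets, at least 3.49-fold higher after overventilation (limma adjusted p = 0.213; 1.13, 1.09 and 3.20 above the floor on the log2 scale on arrays 1 to 3) and at least 1.61-fold higher after LPS (adjusted p = 1). In the overventilated lungs Sprr1a, a gene of the cornified envelope, was at least 2.06-fold higher, the neuropeptide gene Nts at least 2.03-fold, the cytokine gene Il22 at least 1.79-fold and the mucin gene Muc3 at least 1.65-fold, none of them past the test. Il22 was also above the floor on LPS arrays 2 and 3, by 2.23 and 1.46 on the log2 scale against at most 1.25 on an overventilation array. In the other direction 18 probes were above the floor on all controls and at it on all overventilated samples. None was so on all 3 LPS arrays, but most of these 18 were also at the floor on LPS array 2, which held 291 lone low values. Pank1, the pantothenate kinase gene, was at least 3.1-fold lower after overventilation (adjusted p = 0.193) and Klhl24 at least 2.7-fold lower (adjusted p = 0.214). Both were at the floor on LPS array 2. On LPS arrays 1 and 3 Pank1 lay 1.60 and 0.58 above it, and Klhl24 1.56 and 0.97. These genes were named after their values were seen.

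The 139 probes low on overventilation arrays 1 and 3 alone form a pattern that the other arrays do not repeat, since among all other pairs of arrays at most 9 probes were low on both. They include Vegfa, Hif1a, Rpl27 and Atp5l, named after their values were seen, and without overventilation array 2 all 139 were among the 271 probes called lower; with them left out of the test 0 probes were called, a count that follows in part from their choice by low values on these arrays. A general dimness of both arrays would need both floors above those of the 7 arrays without the pattern, which ranged from 0.709 to 1.317. The floor of overventilation array 3 lay above that range, at 2.222, and that of array 1 inside it, at 0.981. This speaks against dimness of array 1 only, and since the scaling between arrays is unknown it does not settle the question. Loss of signal at single probes stays a candidate explanation: 5 genes of the set had a second tested probe, whose median on these arrays was 0.599 against -3.29 for the first probes, as such a loss needs, but second probes did not follow the first in general (median correlation -0.034), which was found after this test was set, so it decides nothing. A response to overventilation that array 2 lacked was not tested and stays open as well.

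Over the tested probes the log2 ratios of LPS array 1 correlated at -0.043 and -0.031 with those of LPS arrays 2 and 3, which correlated at 0.35 with each other, and single genes differed too, such as Cxcl1 at -0.66 against 2.32 and 1.32, F3 at -0.23 against 2.37 and 1.83 and Akap12 at 0.01 against 3.25 and 2.52. The interferon list, whose median on LPS array 1 was 0.889 against 0.263 on the highest control array, goes against a control sample labelled as LPS. That list was picked after the results of these same arrays were seen, and other lists differ. On LPS array 1 the NF-kB list lay at -0.055, inside the range of the controls. The cytokine and immediate early lists lay below the controls there, at -0.375 and -0.249, so the interferon list does not settle this. A shift shared by the arrays numbered 1 may contribute, since deviations from the group means correlated at 0.508, 0.497 and 0.496 between arrays numbered 1 and at most at 0.247 between those numbered 2 or 3. The chemokine list was 0.794 above control array 1 on LPS array 1, inside the range of 0.026 to 0.844 of the other numbers, but at 0.735 it was highest there of the 3 LPS arrays, so a test planned on it leaves this open. A weaker response of that sample to LPS stays open.

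The lower adipose markers after LPS may reflect fat tissue in the samples of control arrays 1 and 2. Control array 3, which had no LPS, lay at -1.68, close to the median of -1.92 of the LPS arrays and far from the mean of 0.89 of the other controls, as this explanation needs, and erythroid and endothelial lists differed by at most 0.122 between control array 3 and the mean of the other controls. Adipoq and Fabp4, abundant transcripts of fat tissue, reached -5.28 and -6.07 on LPS array 2, both lone low spots. On the overventilation arrays Adipoq lay between -2.88 and -0.36 and Fabp4 between -2.14 and -0.23. An effect of LPS on fat transcripts on top of this was not separated from it.

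Other groupings of the arrays were compared by the number of probes at an unadjusted p under 0.05. For overventilation against control the real grouping gave 850, the highest of the others 593, and 1 of the 10 splits, the real one itself, reached that number. For LPS against control these values were 118, 652 and 6, and for overventilation against LPS 543, 818 and 3, the real grouping counted among them, and with 10 splits a share under 0.05 cannot be reached. By the F test 16 of 100 splits of the 9 arrays, the real one included, gave as many as the real 591 probes, so chance is not excluded. The highest, with 1323 probes, set the 3 arrays numbered 1 in a group of their own, and for LPS against control the highest split set control arrays 1 and 3 and LPS array 1 apart. Both splits kept the arrays numbered 1 together. A split of 3 numbered pairs into groups of 3 must part at least 1 pair. That the LPS and control split parted number 3 therefore says nothing against a structure by number. The split with 1323 probes also kept control array 3 with LPS array 3, and LPS array 2 with overventilation array 2. Both splits point to the arrays numbered 1 standing apart and leave a structure by number in general open. Among the 4 splits that part all 3 numbered pairs of LPS and control arrays, the real one gave 118 and the highest other 111.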
